A study of Mus musculus with 24 samples.

How the data were processed

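RNA was sequenced from mouse macrophages by the submitters, from polyadenylated RNA with an unstranded library kit. There were 24 samples: 18 of bone marrow-derived macrophages (BMDMs) in 6 groups of 3, and 6 of the J774.1 line in 2 groups of 3. BMDM groups crossed control, Ctbp1 or Ctbp2 siRNA with vehicle or 4 h of 100 ng/ml LPS. J774.1 groups were wildtype or Ctbp1/2 double knockout, with LPS. BMDM replicates carry the numbers 1, 3 and 4, and J774.1 replicates 1, 2 and 3.

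The deposited tables hold TPM per library, made with Salmon per the file headers, which name gene-level scaled TPM on mm39 for the BMDM libraries. Per the submitters' processing notes, reads were checked with FastQC, quantified with Salmon 1.9.0 and tested with DESeq2 1.44.0 in R 4.4.1, and the notes name mm39, GRCm38 and GRCm39. The authors' deposited tables also give mean normalized counts, a signal averaged over samples, with log2 fold changes, p-values and adjusted p-values from DESeq2. The authors' mean normalized counts sum to 21.3 (BMDM table) and 22.4 (J774.1 table) in units of 1e6. That is no depth per library, and TPM keeps none, so counting error per library is unknown. TPM sums were 999839 to 999944 in BMDM libraries and 999503 to 999526 in J774.1 libraries.

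The BMDM table has 22996 genes. The J774.1 table has 54661 lines for 54380 genes, since 190 identifiers are repeated. No library of the tables was left out. The authors' p-values and fold changes were used only for the side-by-side counts given here. At an adjusted p under 0.05, the authors' deposited table has 4432 genes higher and 4176 lower with LPS, and 4287 of these were called here too, 3986 in the same direction. For the double knockout the authors' deposited table has 2514 higher and 2604 lower, of which 2674 were called here too and 2673 in the same direction. For Ctbp2 siRNA in LPS the authors' deposited table has 299 higher and 164 lower, with 169 called here too. In vehicle it has 159 higher and 64 lower, with 68 called here too. For Ctbp1 siRNA the authors' deposited table has 82 higher and 45 lower in vehicle, 15 called here too, and 17 and 22 in LPS, 12 called here too. The direction was the same for each of these shared calls of the siRNA comparisons. The log2 fold change of Ctbp2 in the double knockout is −0.51 in the authors' deposited table (adjusted p = 4.26e-22), and that of Ctbp1 −3.14.

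The plan written before the data were examined named limma for normalized values. The per-library values are TPM, so limma 3.58.1 in R 4.3.3 was used: lmFit, then eBayes with trend and robust estimation, on log2 of the deposited TPM plus a pseudocount of 1. Genes with a mean of at least 10 TPM over the samples of a fit were tested, 7918 in BMDMs and 7782 in J774.1 cells. The 18 BMDM libraries were fitted together with 1 coefficient per group, and the 6 J774.1 libraries alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 9 comparisons: LPS in control siRNA cells, each siRNA against control in vehicle and in LPS, the 2 interactions of siRNA with LPS, Ctbp2 siRNA against Ctbp1 siRNA in LPS, and the knockout against wildtype. Adjusted p-values in the text come from these limma fits unless a list test or Fisher test is named. Log2 fold changes are limma coefficients, and TPM means are plain means with SD.

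The genes named in the text followed a rule. Ctbp1 and Ctbp2 were always eligible. So were the 8 largest changes in each direction among called genes with a mean of at least 100 TPM and no overlap between the groups' values, or the 5 largest in each direction for an interaction, without the overlap condition. Up to 4 called members of each called list and up to 3 members of the cytokine, chemokine, NF-kB and interferon lists completed it. Pseudogenes and predicted genes were excluded. Not every gene that the rule makes eligible is reported here. Genes named as sets or examples of shared calls, of called list members or of called interaction genes, and Ifnb1 and Pdgfrb, fell outside the rule and were chosen after their values were seen.

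A set of 26 gene lists, 6 of them cell-type markers, was written before the data were examined. Lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison, then again with an estimated correlation. LPS-induced and LPS-repressed classes (at least 2-fold) were taken from libraries outside the comparison: from Ctbp1 siRNA libraries for Ctbp2 siRNA, and the reverse, and from control BMDMs for J774.1 cells. Shared calls were tested with Fisher's exact test over genes tested in both, which takes genes as independent. The plan named the overlap of both siRNAs in LPS and of each siRNA in LPS with the knockout. The overlaps of vehicle with LPS calls, and of Ctbp2 siRNA in vehicle with the knockout, were not in the plan. The comparison of both siRNAs in LPS uses the same controls, so 20 simulations with no true effect were run to estimate the correlation that sharing alone produces.

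The gene tests were tested on simulated data, with 200 changed genes among 7918 or 7782. Each gene had its own spread from these libraries, drawn independently of other genes. At 1.25-fold 50% to 66% of changed genes were recovered (32% and 36% for interactions), at 1.5-fold 86% to 94% (74% and 76%), and at 2-fold 94% to 100%, with 3 to 12 false calls. Of 100 simulated unchanged lists 0 were called by camera and 2 had an unadjusted p under 0.05, and both of 2 shifted lists were called. With genes drawn independently, this cannot show how camera behaves on lists of correlated genes. The estimated correlation in BMDMs was 0.53 for interferon genes and 0.55 for cytokines.

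Alternatives planned before the data were examined were other pseudocounts (0.5 and 8), no filter on low values, quantile normalization, limma without the trend, the replicate number as a block, only the libraries of the groups in the contrast, an estimated correlation for lists, a 2-fold minimum for overlaps, and each library left out in turn. Median-of-ratios scaling of the TPM values, and fits without control siRNA LPS replicate 4 for comparisons that do not include it, were added after the data were seen. Other splits of the samples were counted for each comparison. Tables were summarised with Python 3.11.15 and figures drawn with matplotlib 3.10.9.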

Results

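The libraries measure RNA in mouse macrophages in which the co-repressors CtBP1 or CtBP2 were targeted, nuclear proteins that silence genes through DNA-bound partners. Bone marrow-derived macrophages (BMDMs), primary cells grown from bone marrow, received control siRNA, Ctbp1 siRNA or Ctbp2 siRNA, short RNA duplexes that lower the mRNA of their target. Each then received vehicle or 100 ng/ml lipopolysaccharide (LPS), a bacterial cell wall component that switches on inflammatory genes, for 4 h. J774.1 cells, a macrophage line, were wildtype or labelled as a Ctbp1/2 double knockout, all with LPS. No protein was measured. There were 24 libraries in 8 groups of 3. Values are in TPM, a length-corrected share of each gene in a library's RNA, so library depth is unknown. The labels call the replicates biological but do not say whether they came from separate cultures or animals. The p-values therefore measure the spread between these samples.

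Between 11548 and 12259 genes reached 1 TPM in a BMDM library, and between 11581 and 11823 in a J774.1 library. Mitochondrially encoded genes took 4.10% to 5.22% of BMDM TPM and 5.98% to 6.67% of J774.1 TPM. The lowest correlation between 2 libraries of a group was 0.985. Markers of lymphocytes, stromal cells, mast cells and red cells were near the floor, with no gene above 3.17 TPM on average over vehicle and LPS libraries (Pdgfrb, a stromal marker) in BMDMs. Only 1 of 7 red cell markers and 6 of 11 lymphocyte markers had values for BMDMs, so red cells were hardly tested. Neutrophil markers summed to between 103 and 203 TPM over the BMDM groups and dendritic cell markers to between 119 and 167 TPM, most of it Itgax, which macrophages also express. The tests covered 7918 genes in BMDMs and 7782 in J774.1 cells. The kit keeps no strand, so overlapping and antisense genes cannot be separated, and reads of Rps12, Ptma, Calm3, Hspa1a and Hspa1b cannot be separated from those of close copies.

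Each siRNA lowered its own target and left the paralog uncalled. Ctbp1 fell from 138 ± 7.12 to 57.3 ± 1.96 TPM (SD, n = 3) with Ctbp1 siRNA in vehicle (adjusted p = 8.71e-09) and from 123 ± 7.33 to 50.8 ± 4.46 TPM in LPS (adjusted p = 8.45e-09), so 41.5% of the transcript was left in each. Ctbp2 fell from 52.6 ± 1.41 to 18.2 ± 1.95 TPM with Ctbp2 siRNA in vehicle (34.5% left, adjusted p = 5.69e-08) and from 38.2 ± 1.82 to 12.1 ± 1.70 TPM in LPS (31.7% left, adjusted p = 2.15e-08). Ctbp2 was not called with Ctbp1 siRNA (adjusted p = 0.921 in vehicle, 0.669 in LPS), nor Ctbp1 with Ctbp2 siRNA (0.95 and 0.411). In double knockout J774.1 cells Ctbp1 was at 19.9 ± 3.30 against 161 ± 3.81 TPM in wildtype (12.4% left, adjusted p = 2.17e-07). Ctbp2 transcript was only moderately lower there, at 63.1 ± 1.38 against 78.2 ± 3.52 TPM (80.7% left, adjusted p = 0.000723). TPM for a whole gene does not show whether the remaining Ctbp2 transcript encodes protein.

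**Figure D1:**
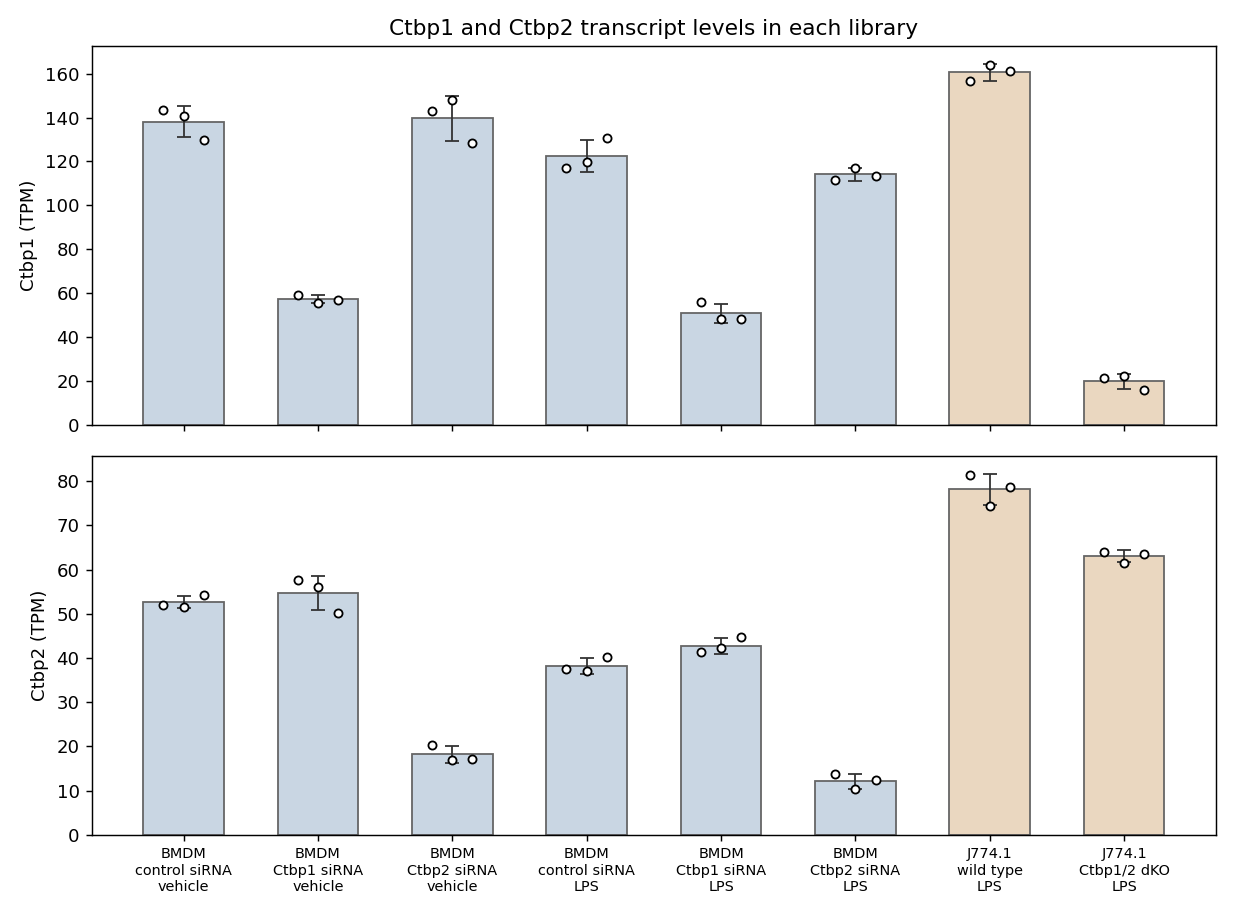
Ctbp1 and Ctbp2 in every library, in TPM. Ctbp2 kept 80.7% of its wildtype level in double knockout J774.1 cells.

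The question of the first comparison was what LPS changes in BMDMs with control siRNA. Chemokines and cytokines were among the genes that rose. Cxcl3, a neutrophil attractant, rose from 0.0997 ± 0.173 to 1656 ± 641 TPM (SD, n = 3; log2 fold change 10.48, adjusted p = 1.63e-15), and Il1b from 1.9 ± 0.341 to 2018 ± 786 TPM (9.36, 2.75e-13). Acod1, which makes itaconate, rose from 3.11 ± 0.452 to 3668 ± 488 TPM (9.80, 2.57e-21), and Tnf from 37.1 ± 0.639 to 4314 ± 988 TPM (6.80, 7.79e-18). Arhgap25, a Rac regulator, fell from 251 ± 14.2 to 19.8 ± 4.82 TPM (−3.63, 1.23e-14). Rab7b and Rgs2 fell too, by −2.90 and −2.85 on the log2 scale. The replication gene Mcm7 fell from 35.2 ± 1.65 to 11.1 ± 2.05 TPM (−1.59, 1.02e-09). Ctbp2 fell by −0.45 (adjusted p = 0.000171). Ctbp1 was called lower (−0.17, 0.0249), but after median-of-ratios scaling it was at +0.04 (0.62). Its call was also lost without control siRNA LPS replicate 1 or 3, or vehicle replicate 1 or 3, with adjusted p up to 0.0986.

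Among lists of genes fixed in advance, all 28 tested members of the NF-kB list, inhibitors and targets of that inflammatory transcription factor, rose with LPS (28 also adjusted over the list alone). Nfkbia reached 1043 ± 105 from 65.8 ± 0.633 TPM. The list test called it higher (adjusted p = 6.81e-28; adjusted p = 0.0586 with an estimated correlation). Of 13 cytokines 12 rose (12 adjusted over the list alone; list test 1.59e-10; adjusted p = 0.176 with an estimated correlation), and of 16 chemokines 14 (14 adjusted over the list alone; 1.88e-11; adjusted p = 0.118 with an estimated correlation). Of 35 interferon response genes 30 rose and 1 fell (30 and 1 adjusted over the list alone; 5.0e-13; adjusted p = 0.279 with an estimated correlation), among them Gbp2 (324 ± 59.5 against 14.7 ± 1.59 TPM) and Irf1 (531 ± 45.0 against 57.8 ± 1.87 TPM). After median-of-ratios scaling 32 interferon genes rose and 0 fell. Of 15 MHC genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; 0.000196; adjusted p = 0.279 with an estimated correlation). Of 27 cell cycle genes 24 fell, such as Pcna and E2f1, and 1 rose (24 and 1 adjusted over the list alone; 0.00467; adjusted p = 0.728 with an estimated correlation). With control siRNA LPS replicate 4 left out, the estimated correlation gave 0.000314 for NF-kB genes, 0.0361 for cytokines and 0.0067 for chemokines, but 0.239 for interferon genes, 0.239 for MHC genes and 0.637 for cell cycle genes.

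Summed neutrophil markers were at 183 TPM with LPS against 124 TPM without it, and dendritic cell markers at 147 against 124 TPM. Stromal markers summed to 6.46 TPM with LPS against 0.215 TPM without it. In all, 6053 of 7918 genes were called with LPS, 1847 higher and 4206 lower, and 1333 changed at least 2-fold (564 higher, 769 lower). The median of all tested genes was −0.21 on the log2 scale, and TPM values of a library sum to a fixed total. After median-of-ratios scaling 2862 genes were higher and 2805 lower, so the share of higher calls went from 30.5% to 50.5%. Genes with a modest fall in TPM, such as Ctbp1, have to be read relative to that shift.

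Control siRNA LPS replicate 4 stood apart from replicates 1 and 3. Among 135 genes that LPS strongly induced in the Ctbp1 siRNA libraries, 131 were lower in it, with a median of −0.45 on the log2 scale. The 127 strongly repressed genes were higher by a median of 0.47. In replicates 1 and 3 these medians were 0.19 and 0.24 for induced genes, −0.21 and −0.26 for repressed genes. Each Ctbp1 siRNA and Ctbp2 siRNA library in LPS stayed between −0.051 and 0.038 for induced genes. That replicate is 1 of the 3 controls for each siRNA comparison in LPS, and it also widens the common estimate of spread in BMDMs.

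**Figure D2:**
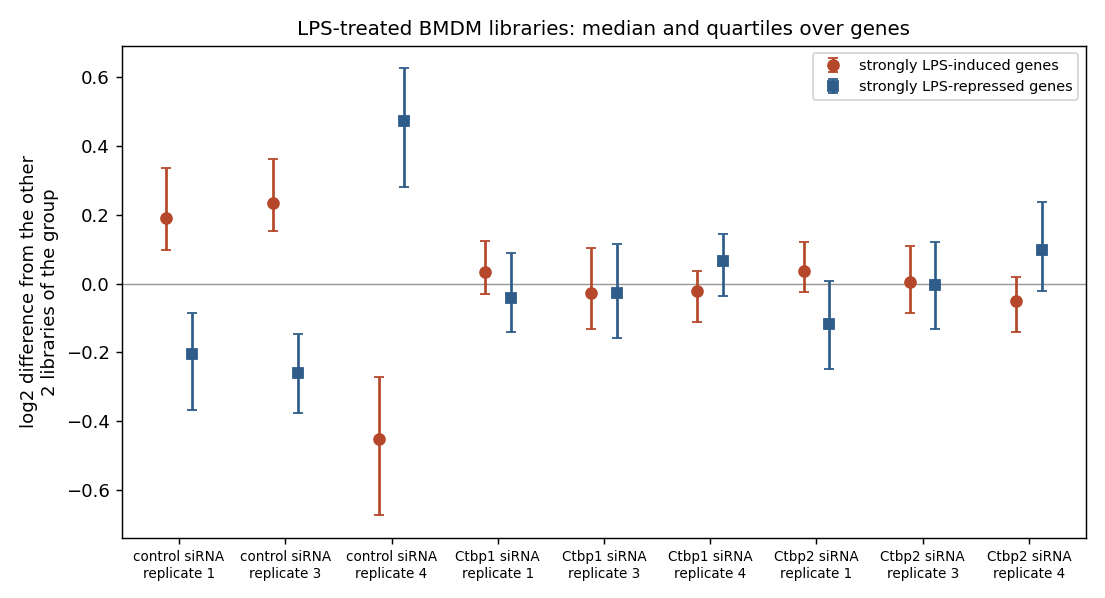
Median deviation of strongly LPS-induced and LPS-repressed genes in each LPS library from the other libraries of its group. Control siRNA replicate 4 was at −0.45 for induced genes and 0.47 for repressed genes.

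Ctbp1 siRNA was compared with control siRNA to ask which genes change with it at rest and under LPS. A response to the Ctbp1 siRNA duplex itself cannot be told apart from loss of Ctbp1 here. The test called 17 genes in vehicle and 12 in LPS. Pdia3, a disulfide isomerase of the endoplasmic reticulum, fell from 364 ± 4.80 to 255 ± 5.44 TPM in vehicle (SD, n = 3; −0.51, adjusted p = 1.82e-07) and from 321 ± 7.67 to 226 ± 5.05 TPM in LPS (−0.50, 2.26e-07). Slc25a5, which exchanges ADP and ATP across the mitochondrial membrane, fell from 341 ± 10.9 to 254 ± 10.2 TPM in vehicle (−0.42, 0.000256) and from 279 ± 9.18 to 211 ± 5.91 TPM in LPS (−0.41, 0.000441). These genes and Ctbp1 itself kept their calls without each library in turn. Inflammatory genes were not called: with Ctbp1 siRNA in LPS Cxcl10 was at 532 ± 58.0 against 659 ± 144 TPM (adjusted p = 0.87), and in vehicle Nfkbiz was at −0.31 (0.108). In vehicle 1 NF-kB gene and the NF-kB list were called lower without control siRNA LPS replicate 4 (0.0421; adjusted p = 0.944 with an estimated correlation), against 0.23 for the list with all libraries.

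In vehicle, 17 genes were called with Ctbp1 siRNA, 4 higher and 13 lower (9 and 18 after median-of-ratios scaling). The count was 5 without Ctbp1 siRNA vehicle replicate 1, 7 without its replicate 3 or 4 or control vehicle replicate 1 or 4, and 43 without control siRNA LPS replicate 4. It was 35 with only the 6 libraries compared. In LPS 12 genes were called, 2 higher and 10 lower. That count was 133 without control siRNA LPS replicate 4, 96 higher and 37 lower. It was 6 without Ctbp1 siRNA LPS replicate 3, 7 without its replicate 1 or control replicate 1 or 3, and 2 with only the 6 libraries compared. The vehicle and LPS calls came from separate libraries, and 7 genes fell in both (0.0164 by chance, Fisher p = 5.32e-19): Ctbp1, Pdia3, Slc25a5, Rab8b, Atp6v0d1, Fxyd2 and 1110008P14Rik. Both comparisons use the same spread estimate for a gene, so the calls are not independent as the chance count assumes. Rab8b (adjusted p = 0.0325 in vehicle, 0.0419 in LPS) and Atp6v0d1 (0.0422, 0.0359) were less firm. In vehicle Atp6v0d1 lost its call without each of the 6 libraries (up to 0.161) and Rab8b without each but control replicate 1 (up to 0.144). In LPS Atp6v0d1 lost it without each but control replicate 4 (up to 0.21), and Rab8b without Ctbp1 siRNA replicate 3 or 4 or control replicate 1 or 3 (up to 0.242).

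The mitochondrially encoded list was lower with Ctbp1 siRNA in vehicle (median −0.17 over 13 genes, adjusted p = 7.67e-07; adjusted p = 0.0901 with an estimated correlation). Only mt-Cytb was called in it, and 5 genes fell adjusted over the list alone. The mt-Cytb call (2817 ± 129 against 3304 ± 138 TPM, adjusted p = 0.0287) was lost without Ctbp1 siRNA vehicle replicate 1 or 3 or control replicate 1, with adjusted p up to 0.144. In LPS the interferon response list was lower with Ctbp1 siRNA (median −0.21 over 35 genes, 4.91e-14; adjusted p = 0.6 with an estimated correlation). None of its genes was called by limma, over all genes or adjusted over the list alone. Without control siRNA LPS replicate 4, 2 interferon genes and 4 of 13 cytokines were lower, and the lists of cytokines (2.29e-09; adjusted p = 0.0602 with an estimated correlation) and NF-kB genes (median −0.12, 3.82e-11; adjusted p = 0.0203 with an estimated correlation) were called lower. Chemokines (5.58e-06; adjusted p = 0.0602 with an estimated correlation) and MHC genes (0.00201; adjusted p = 0.349 with an estimated correlation) were called lower too, and cell cycle genes higher (0.000111; adjusted p = 0.544 with an estimated correlation). With all libraries none of these lists was called (0.655 for cytokines, 0.269 for NF-kB genes, 0.655 for chemokines, 0.116 for MHC genes, 0.288 for cell cycle genes). Stress response genes were lower as a list (median −0.08 over 12 genes, 0.00917; adjusted p = 0.209 with an estimated correlation), again with no gene called.

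For Ctbp2 siRNA the same question was asked first in vehicle. Of 35 interferon response genes 10 rose, while the list test was lost with an estimated correlation (adjusted p = 0.121). Ifit2, which binds viral RNA, went from 30.2 ± 5.15 to 55.7 ± 5.98 TPM (SD, n = 3; 0.87, adjusted p = 0.00663). Rtp4 went from 148 ± 13.4 to 214 ± 19.4 TPM (0.53, 0.00663). Outside that list Il1rn, the interleukin-1 receptor antagonist, rose from 205 ± 8.87 to 327 ± 46.8 TPM (0.66, 0.0105). Shisa5 rose to 535 ± 8.45 from 433 ± 8.05 TPM (0.30, 0.00818). Ptma fell from 1008 ± 44.2 to 797 ± 17.5 TPM (−0.34, 0.00275) and Arl8a, a lysosomal GTPase, from 191 ± 6.25 to 161 ± 1.97 TPM (−0.25, 0.00663). These calls held without each library in turn. Ifit3 (87.3 ± 11.6 against 46.6 ± 11.1 TPM, adjusted p = 0.0117) lost its call without control vehicle replicate 1 (0.0656) or 3 or Ctbp2 siRNA replicate 4. Xaf1 (96.4 ± 7.77 against 70.1 ± 5.46 TPM, 0.0109) lost it without Ctbp2 siRNA vehicle replicate 1 or 4 (0.0642) or control replicate 3.

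The interferon response list was the clearest group with Ctbp2 siRNA in vehicle. Of 35 genes 10 rose, 0 fell and 33 had a higher estimate (27 rose adjusted over the list alone). Examples were Ifit1, Ifit2, Ifit3, Isg15 and Rsad2. Ifit2 and Rtp4 kept their calls without each library in turn. Oasl2 (adjusted p = 0.0491) lost its call without each of the 6 libraries but control replicate 4, with adjusted p up to 0.185. The list median was 0.35 (adjusted p = 1.54e-32; adjusted p = 0.121 with an estimated correlation). With Ctbp1 siRNA in vehicle the same list had a median of 0.03 and was not called (0.713). Of 15 MHC genes 3 rose, B2m, Tapbp and H2-D1 (6 adjusted over the list alone; 0.000202; adjusted p = 0.303 with an estimated correlation). The B2m call (6455 ± 195 against 5428 ± 280 TPM, adjusted p = 0.0263) was lost without Ctbp2 siRNA vehicle replicate 1 or 4 or control replicate 1 or 3, with adjusted p up to 0.118. Tapbp (0.0491) lost its call without each of the 6 libraries (up to 0.203), and H2-D1 (0.0456) without each but Ctbp2 siRNA replicate 3 (up to 0.185). Mitochondrially encoded genes were lower (median −0.14 over 13, 2 called and 6 adjusted over the list alone; 0.000277; adjusted p = 0.157 with an estimated correlation). Of 6 other called lists none held with an estimated correlation. Chemokines were higher (median 0.05, 1 of 16 called and 2 adjusted over the list alone; 0.00243; adjusted p = 0.481 with an estimated correlation) and cell cycle genes lower (median −0.16 over 27, 0 called by limma over all genes or adjusted over the list alone; 0.0429; adjusted p = 0.75 with an estimated correlation). Neither the cytokine list (0.468) nor the NF-kB list (0.615) was called.

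In all, 81 genes were called with Ctbp2 siRNA in vehicle, 40 higher and 41 lower. After median-of-ratios scaling 63 were higher and 29 lower. The count was 21 without Ctbp2 siRNA vehicle replicate 1, 46 without replicate 3 and 32 without replicate 4. It was 22, 32 and 52 without control vehicle replicates 1, 3 and 4, and 147 without control siRNA LPS replicate 4.

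With Ctbp2 siRNA in LPS, 4 of 16 immediate early genes and 3 of 28 NF-kB and feedback genes rose, by small amounts. Egr2, an immediate early transcription factor, went from 50.4 ± 3.29 to 74.6 ± 5.81 TPM (SD, n = 3; 0.56, adjusted p = 0.000112) and Ier2 from 42.2 ± 5.17 to 64.6 ± 3.77 TPM (0.61, 0.000914). Junb reached 482 ± 14.8 against 393 ± 32.8 TPM (0.30, 0.00787), and Zfp36, which destabilises cytokine mRNA, 366 ± 19.9 against 298 ± 14.3 TPM (0.29, 0.0099). Il1rn rose to 314 ± 58.2 from 203 ± 11 TPM (0.62, 0.00838) and the NF-kB cofactor Bcl3 to 107 ± 8.81 from 81.5 ± 1.29 TPM (0.39, 0.00894). Ptma fell from 761 ± 17.2 to 556 ± 20.9 TPM (−0.45, 7.4e-05), Tor3a from 91.0 ± 5.68 to 67.8 ± 3.85 TPM (−0.42, 0.000722), and the scavenger receptor Lrp1 from 261 ± 44.4 to 186 ± 5.53 TPM (−0.47, 0.0038). These calls held without each library in turn, but with only the 6 libraries compared just Ptma (0.0194) and Ctbp2 kept theirs, and Egr2 was at 0.0572. Tnf was not called (5417 ± 159 against 4314 ± 988 TPM, 0.0916), nor Csf2 (64.8 ± 22.7 against 35.4 ± 16.9 TPM, 0.108). Ccl22 was called (84.0 ± 13.7 against 50.1 ± 17.4 TPM, 0.0489) and lost its call without any of the Ctbp2 siRNA LPS replicates or control replicate 4, with adjusted p up to 0.156.

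The AP-1 and immediate early list was higher with Ctbp2 siRNA in LPS: 4 of 16 genes rose, Egr2, Fosl2, Ier2 and Junb (5 adjusted over the list alone; median 0.13, adjusted p = 6.88e-09; adjusted p = 0.00218 with an estimated correlation). Fosl2 (adjusted p = 0.0221) lost its call without Ctbp2 siRNA LPS replicate 1 (0.108) or 3 or control replicate 4. In the glycolysis list 4 of 22 rose, Hk2, Slc2a1, Slc16a3 and Pgk1 (5 higher and 1 lower adjusted over the list alone; median 0.07, 1.04e-07; adjusted p = 0.036 with an estimated correlation). Without control siRNA LPS replicate 4 the glycolysis list was at 0.0599 with an estimated correlation, with 2 genes called. Slc2a1 (158 ± 6.67 against 131 ± 10.1 TPM, 0.0101) lost its call without Ctbp2 siRNA LPS replicate 1 (0.0576). Slc16a3 (0.0264) lost it without Ctbp2 siRNA LPS replicate 1 (0.117) or 3 or control replicate 4, and Pgk1 (0.0416) without Ctbp2 siRNA LPS replicate 1 (0.136) or 3 or control replicate 3 or 4. Over all comparisons 50 of 186 list tests were called, and only 4 held with an estimated correlation: these 2 lists here and in Ctbp2 siRNA against Ctbp1 siRNA in LPS. Both comparisons use the same Ctbp2 siRNA LPS libraries, so their list calls are not independent.

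The cytokine, chemokine and NF-kB lists leaned higher with Ctbp2 siRNA in LPS. Their few called genes included the interleukin-1 receptor antagonist Il1rn and Zfp36, which destabilises cytokine mRNA, while Tnf and Csf2 were not called. Of 13 cytokines 1 rose, Il1rn (5 adjusted over the list alone; median 0.34, adjusted p = 1.04e-07; adjusted p = 0.186 with an estimated correlation), of 16 chemokines 2 rose, Ccl8 and Ccl22 (2 adjusted over the list alone; median 0.33, 8.2e-10; adjusted p = 0.087 with an estimated correlation), and of 28 NF-kB genes 3 rose, Bcl3, Zfp36 and Zc3h12a (4 adjusted over the list alone; median 0.12, 7.89e-11; adjusted p = 0.165 with an estimated correlation). These medians were 0.15, 0.15 and 0.01 without control LPS replicate 4. Zc3h12a (0.0416) lost its call without each library but control LPS replicate 3, with adjusted p up to 0.145. Interferon genes were not called as a list (median −0.12, 0.196). Of 35 only Tor3a fell (2 adjusted over the list alone), but without control siRNA LPS replicate 4 4 fell and the list was called lower (8.26e-07; adjusted p = 0.401 with an estimated correlation). After median-of-ratios scaling its list test was at 0.0486. Cell cycle genes were lower as a list (median −0.23 over 27, 0 called by limma over all genes or adjusted over the list alone; 0.000927; adjusted p = 0.694 with an estimated correlation), and not without that replicate (0.144). Of 8 glucocorticoid target genes Mt2 rose (3 adjusted over the list alone). The median of that list was −0.00 and its mean 0.07, and the list test called it higher (0.0143; adjusted p = 0.087 with an estimated correlation), but not after median-of-ratios scaling (0.087).

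**Figure D3:**
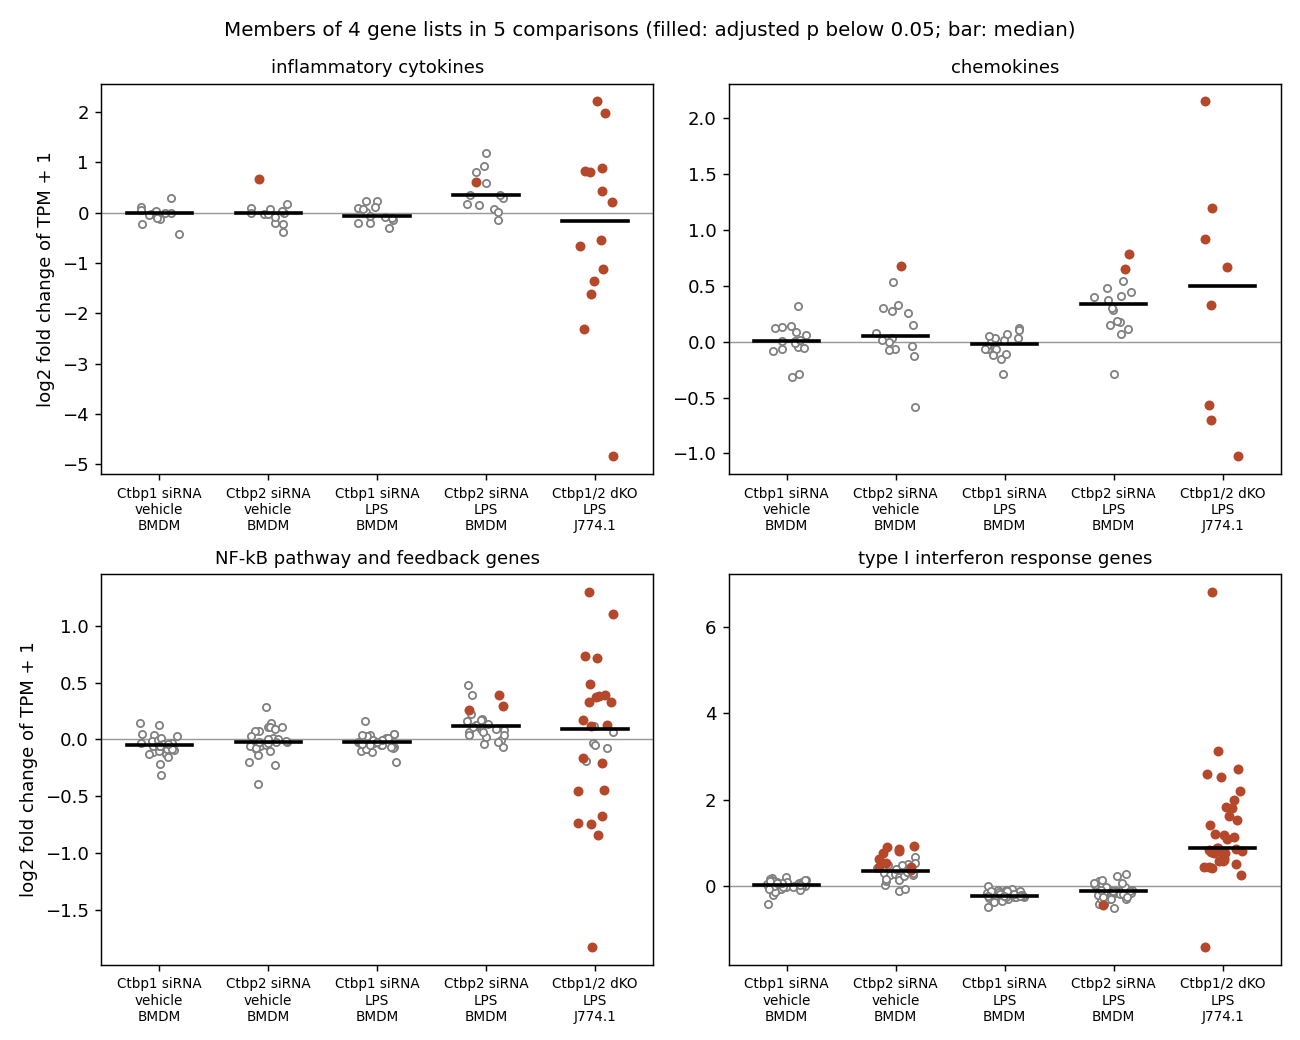
Log2 fold changes of the members of fixed lists in each siRNA and knockout comparison. The interferon response list had a median of 0.35 with Ctbp2 siRNA in vehicle and −0.12 with Ctbp2 siRNA in LPS.

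In all, 251 genes were called with Ctbp2 siRNA in LPS, 61 higher and 190 lower (24.3% higher). After median-of-ratios scaling 127 were higher and 81 lower (61.1% higher), with 142 genes called both ways. Only Ctbp2 changed at least 2-fold. The count was 107 without Ctbp2 siRNA LPS replicate 1, 125 without its replicate 3, and 161 without control replicate 4. With only the 6 libraries compared it was 4, so most calls rest on the spread estimated from all 18 BMDM libraries. Calls in vehicle and LPS came from separate libraries and overlapped: 9 genes were higher in both (0.308 by chance, Fisher p = 1.18e-11) and 20 lower in both (0.984 by chance, 2.54e-22). The 20 include Ctbp2, the siRNA target. Both comparisons use the same spread estimate for a gene, so the calls are not independent as the chance counts assume. The 9 were Il1rn, Ccl8, Ctss, Fgfr1, Hspa1a, Hspa1b, Serpinb9b, Smpdl3a and H2-D1, of which 0 are in the interferon list. The number was 14 without control siRNA LPS replicate 4.

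Whether Ctbp2 siRNA bears on LPS-regulated genes as a class was asked with classes taken from the Ctbp1 siRNA libraries. The 559 LPS-induced genes had a median of 0.05 with Ctbp2 siRNA in LPS (19 higher, 4 lower) and the 703 repressed genes a median of −0.13 (4 higher, 30 lower; Fisher p = 1.33e-07). The median of all tested genes was −0.05. Leaving out control siRNA LPS replicate 4, the induced median was −0.01 (11 higher, 11 lower), the repressed median −0.03 (11 higher, 15 lower), and the Fisher p 0.772. With all libraries and median-of-ratios scaling the medians were 0.11 (31 higher, 5 lower) and −0.08 (5 higher, 15 lower; Fisher p = 7.81e-06). With Ctbp1 siRNA in LPS the induced and repressed medians were −0.01 and 0.03, with 0 and 2 genes called by limma. Without that replicate 14 induced genes were lower and 59 repressed genes higher (3.64e-12). For Ctbp1 siRNA both medians kept their sign without it (−0.09 and 0.12), and for Ctbp2 siRNA the induced median turned.

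Interaction tests asked whether the response to LPS itself differed. With Ctbp2 siRNA 8 genes did. In control siRNA cells Ifit2 went from 30.2 ± 5.15 to 149 ± 22.9 TPM (SD, n = 3) with LPS, in Ctbp2 siRNA cells from 55.7 ± 5.98 to 105 ± 9.41 TPM (difference in log2 fold change −1.37, adjusted p = 0.00891). Ifit3 responses differed by −1.31 (0.033), from 87.3 ± 11.6 to 77.4 ± 6.20 TPM in Ctbp2 siRNA cells. Xaf1 differed by −0.69 (0.0236), Irgm1 by −0.69 (0.0333) and Tor3a by −0.58 (0.00891). Tgtp2 and Gm13464 also responded less, and Egr2 more (0.48, 0.033). Only Tor3a was called without each library in turn, with adjusted p up to 0.0381. Ifit2 was at 0.0508 without control vehicle replicate 1, and it kept its call without each other library. Ifit3 (up to 0.127) and Irgm1 (up to 0.149) lost their calls in 9 of 12 leave-one-out fits, Egr2 in 8 (up to 0.127) and Xaf1 in 7 (up to 0.102). All 4 lost them without control vehicle replicate 1 or 3, control LPS replicate 1 or 3, Ctbp2 siRNA vehicle replicate 4 or Ctbp2 siRNA LPS replicate 3. Tnf (0.44, 0.408) and Ccl22 (0.85, 0.378) were not called.

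The count of 8 for Ctbp2 siRNA was 4, 2 and 5 without Ctbp2 siRNA LPS replicates 1, 3 and 4, 3 without Ctbp2 siRNA vehicle replicate 3 or 4, and 3 or 2 without control LPS replicate 1 or 3. It was 1 and 4 without control vehicle replicates 1 and 3, 15 without control vehicle replicate 4 and 38 without control LPS replicate 4. After median-of-ratios scaling it was 2. With Ctbp1 siRNA 1 gene responded differently, Rps12 (0.45, adjusted p = 0.0412), and it was lost in 11 of 12 leave-one-out fits (up to 0.2). It was kept only without control LPS replicate 4, which left 9 genes. The interferon list responded less with Ctbp2 siRNA: 34 of 35 estimates were lower and 4 genes called (26 adjusted over the list alone; median −0.45, 4.76e-27; adjusted p = 0.13 with an estimated correlation), or 11 without control LPS replicate 4. With Ctbp2 siRNA the list was higher in vehicle (median 0.35) and not called in LPS (list test adjusted p = 0.196). The difference in response thus includes the higher vehicle level.

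Ctbp2 siRNA against Ctbp1 siRNA in LPS asked how the 2 siRNA treatments differ. Responses to the duplexes themselves cannot be told apart from loss of the paralogs. The treatments also left unlike shares of their targets, 31.7% of Ctbp2 and 41.5% of Ctbp1 transcript. The control libraries enter only the estimate of the spread. Pdia3 was higher with Ctbp2 siRNA (314 ± 4.41 against 226 ± 5.05 TPM, SD, n = 3; 0.47, adjusted p = 4.08e-07), as was Mdfic (202 ± 3.03 against 151 ± 5.47 TPM; 0.42, 0.000719). Junb was at 482 ± 14.8 against 390 ± 11.1 TPM (0.30, 0.00507) and Egr2 at 74.6 ± 5.81 against 58.8 ± 1.88 TPM (0.34, 0.00564). Ptma was lower (556 ± 20.9 against 796 ± 53.6 TPM; −0.51, 5.69e-06), as were Cyria (162 ± 3.52 against 223 ± 5.30 TPM; −0.46, 0.000336) and the ATP-gated channel P2rx4 (196 ± 5.33 against 256 ± 11.9 TPM; −0.38, 0.000398). Tnf was higher (5417 ± 159 against 4054 ± 23.0 TPM; 0.42, 0.037), as was Il12b (138 ± 24.4 against 67.2 ± 4.59 TPM; 1.01, 0.0359). Both cytokines lost their calls without each of the 6 libraries, with adjusted p up to 0.112 for Tnf and 0.102 for Il12b.

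Of 16 AP-1 genes 3 were higher than with Ctbp1 siRNA, Egr2, Ier2 and Junb (4 adjusted over the list alone; adjusted p = 3.04e-07; adjusted p = 0.00629 with an estimated correlation), and of 22 glycolysis genes 3, Slc16a3, Hk2 and Pgk1 (4 adjusted over the list alone; 3.04e-07; adjusted p = 0.0452 with an estimated correlation). Cytokines were higher as a list (3 of 13 called, Csf2, Il12b and Tnf, 4 adjusted over the list alone; median 0.38, 3.12e-08; adjusted p = 0.131 with an estimated correlation), as were chemokines (1 of 16, 4 adjusted over the list alone; median 0.38, 2.37e-10; adjusted p = 0.1 with an estimated correlation) and NF-kB genes (3 of 28, 8 adjusted over the list alone; median 0.15, 5.5e-14; adjusted p = 0.114 with an estimated correlation). Fitted without control LPS replicate 4, which enters only the spread, 9 cytokines, 7 chemokines and 10 NF-kB genes were called higher, and the lists were at 0.02, 0.00453 and 0.00188 with an estimated correlation. Cell cycle genes were lower: 6 of 27 were called, Aurka, Birc5, Cdk1, Kif11, Pcna and Top2a (16 adjusted over the list alone; median −0.33, 2.39e-05; adjusted p = 0.48 with an estimated correlation). After median-of-ratios scaling 2 were called, and without control LPS replicate 4 13. The Aurka call (7.77 ± 0.0799 against 11.6 ± 1.55 TPM, 0.0138) was lost without Ctbp1 siRNA LPS replicate 3 (0.0572) or 4. Of the others fitted without each library, Pcna (0.0373) lost its call without any of the 6 (up to 0.125), Birc5 (0.0295) without Ctbp1 siRNA replicate 3 or 4 or Ctbp2 siRNA replicate 1 or 4 (up to 0.114), and Kif11 (0.0277) without Ctbp1 siRNA replicate 3 or 4 or Ctbp2 siRNA replicate 1 or 3 (up to 0.119). Hk2 (0.0429, up to 0.179) lost it without Ctbp1 siRNA replicate 3 or 4 or Ctbp2 siRNA replicate 1 or 4, Pgk1 (0.0387, up to 0.128) without any but Ctbp2 siRNA replicate 4, and Csf2 (0.0435, up to 0.141) without any but Ctbp1 siRNA replicate 3.

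In all, 538 genes differed between the siRNAs in LPS, 104 higher and 434 lower with Ctbp2 siRNA (19.3% higher), and 210 and 120 after median-of-ratios scaling (63.6% higher). The count was 213 and 166 without Ctbp1 siRNA LPS replicates 3 and 4, 162, 323 and 340 without Ctbp2 siRNA LPS replicates 1, 3 and 4, and 1066 without control LPS replicate 4. With only the 6 libraries compared it was 138. Against control siRNA, 251 genes were called with Ctbp2 siRNA and 12 with Ctbp1 siRNA, but 161 and 133 without control LPS replicate 4, and 4 and 2 with only the 6 libraries compared.

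In J774.1 cells the double knockout was compared with wildtype under LPS. Of 35 interferon response genes 34 were higher and 1 lower (median 0.88; the list call was lost, at adjusted p = 0.307 with an estimated correlation). The largest rises included Rsad2 and Ifit2. Rsad2, an antiviral enzyme, was at 216 ± 10.8 against 0.968 ± 0.367 TPM (SD, n = 3; log2 fold change 6.80, adjusted p = 3.65e-09) and Ifit2 at 151 ± 10.4 against 16.4 ± 1.31 TPM (3.12, 9.11e-09). The MHC class II gene H2-Aa was at 21.1 ± 0.580 TPM and listed at 0 in wildtype (adjusted p = 4.96e-09). S100a11 rose to 1179 ± 19.4 from 205 ± 10.2 TPM (2.52, 2.52e-09), and the chemokine Ccl22 to 765 ± 29.2 from 171 ± 3.12 TPM (2.15, 2.52e-09). Il1a rose to 331 ± 15.6 from 83.7 ± 3.47 TPM (1.97, 1.02e-08). Adgre1, which encodes the macrophage marker F4/80, fell from 225 ± 5.24 to 15.8 ± 1.39 TPM (−3.75, 2.52e-09). It was 1 of 3 lower genes in the macrophage identity list, where 8 of 11 were higher (8 and 3 adjusted over the list alone; median 0.40, mean −0.16). The list test pointed higher and was not called (0.147). Csf2 fell from 35.5 ± 1.91 to 0.297 ± 0.282 TPM (−4.84, 7.54e-08), Pla2g5 from 449 ± 9.87 to 40.9 ± 3.18 TPM (−3.43, 2.52e-09) and Odc1, which makes polyamines, from 4917 ± 21.7 to 1433 ± 15.3 TPM (−1.78, 4.54e-10). Csf3, Cxcl2 and Nfkbiz fell by −1.63, −1.03 and −1.82 on the log2 scale.

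Of 35 interferon response genes 34 were higher in the double knockout and 1 lower, Ifnb1 (34 and 1 adjusted over the list alone; median 0.88, adjusted p = 5.39e-19; adjusted p = 0.307 with an estimated correlation). Each of 11 MHC genes was higher, such as Psmb8 and Cd74 (11 adjusted over the list alone; median 0.78, 1.27e-08; adjusted p = 0.161 with an estimated correlation). Dendritic cell markers summed to 7.34 TPM against 1.40 TPM in wildtype, all below the level tested. Cell cycle genes were lower, 19 of 30 with 1 higher (20 and 1 adjusted over the list alone; median −0.25, 7.52e-09; adjusted p = 0.161 with an estimated correlation), such as Cdk1 (221 ± 11.2 against 319 ± 9.18 TPM). Of 6 glucocorticoid target genes 4 fell, Errfi1, Mt2, Mt1 and Per1 (4 adjusted over the list alone; median −0.52, 0.00167; adjusted p = 0.161 with an estimated correlation). Of 12 stress response genes 8 fell, such as Chac1 and Atf5, and 1 rose, Slc7a11 (8 and 1 adjusted over the list alone; median −0.26, 0.00555; adjusted p = 0.68 with an estimated correlation). Cytokines split, with 7 higher and 7 lower of 14 (7 and 7 adjusted over the list alone; 0.441), and NF-kB genes too, with 13 higher and 9 lower of 28 (14 and 9 adjusted over the list alone; 0.989). The NF-kB median was 0.09 and its mean 0.01, while the list test pointed lower.

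In all, 3272 of 7782 genes were called in the double knockout, 1979 higher and 1293 lower, and 241 changed at least 2-fold (181 higher, 60 lower). After median-of-ratios scaling 1709 were higher and 1638 lower. Quantile normalization gave 1480 higher and 1888 lower (43.9% higher, against 60.5% as reported), so the majority direction depends on the normalization. The labels give no number of knockout clones. Differences between clones can therefore not be told apart from an effect of the knockout in any of these calls.

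The last comparison asked whether the calls of the siRNA and knockout comparisons meet. Higher calls with Ctbp2 siRNA in vehicle BMDMs met those of the double knockout in LPS: 23 genes were higher in both (7.42 by chance, Fisher p = 1.12e-09), 10 of them in the interferon list and 13 outside it, such as Ly6e, B2m, Tapbp, H2-D1 and Ifitm3. This overlap was not in the plan and sets vehicle cells against LPS cells. Fisher's test takes genes as independent, while the interferon list had an estimated correlation of 0.53 in BMDMs. The list is a fixed selection, so a gene outside it may still respond to interferon. The number higher in both was 41 without control siRNA LPS replicate 4 (14.6 by chance). Of lower calls 10 met (5.62 by chance, Fisher p = 0.0602), or 17 without that replicate (10.8 by chance, 0.0443). With Ctbp2 siRNA in LPS 10 genes were higher in both (10.3 by chance, Fisher p = 1) and 17 lower in both (24.1 by chance, 0.116), and 77 went opposite ways. Without that replicate 16 were higher in both (10.3 by chance, Fisher p = 0.0455), 11 lower in both (13.3 by chance, 0.55) and 46 opposite. After median-of-ratios scaling 51 went opposite ways. No chance count was made for opposite calls, so whether they exceed chance was not tested. Of 6544 genes tested in both with all libraries, Ctbp2 siRNA in LPS had 39 higher and 150 lower. The knockout had 1734 higher and 1050 lower. Across genes the log2 fold changes correlated weakly and negatively. The value of r was −0.080 with all libraries, −0.085 without that replicate and −0.079 after median-of-ratios scaling. Csf2 and Nfkbiz are examples of genes lower in the knockout but not called with Ctbp2 siRNA in LPS. After median-of-ratios scaling 37 were higher in both (22.9 by chance, 0.0016). With Ctbp1 siRNA in LPS 1 was higher and 2 lower in both, or 32 higher (18 by chance, Fisher p = 0.000263) and 9 lower (4.34 by chance, 0.0297) without that replicate. Both siRNAs in LPS called 1 gene the same way, Pcp4l1, which was lower. Sharing the 3 control libraries with no true effect gave a mean of 10.9 such genes in 20 simulations, 3 at least and 20 at most. Leaving out control siRNA LPS replicate 4 gave 17, with 10 higher and 7 lower, and no simulation was run for that setting. The log2 fold changes of both siRNAs correlated across genes with r = 0.368 in all libraries. That was below all 20 simulations with shared controls (mean 0.537, lowest 0.458). The simulations do not reproduce these libraries, so they give no baseline for what the siRNAs share.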

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

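The tests of control siRNA LPS replicate 4, the mixing and duplex tests of the interferon genes, and both tests of the direction of calls were chosen only after those results were seen. Median-of-ratios scaling, used for the interferon genes too, was also chosen after the data were seen, and the splits of the samples were planned.

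Differences between the LPS responses of siRNA groups were tested with interaction terms. For Ctbp2 siRNA 8 genes differed, and for Ctbp1 siRNA 1 gene, Rps12. Interferon response genes responded less than with control siRNA as a list, with a median difference of −0.45 for Ctbp2 siRNA and −0.23 for Ctbp1 siRNA. For Ctbp2 siRNA that difference includes the higher level of the list in vehicle. With Ctbp2 siRNA the median differences of other called lists were 0.44 for cytokines, 0.15 for chemokines, 0.12 for NF-kB genes, 0.037 for AP-1 and immediate early genes, 0.012 for glycolysis genes, −0.14 for MHC genes and 0.12 for mitochondrially encoded genes. With Ctbp1 siRNA that of mitochondrially encoded genes was 0.20. None of these list calls held with an estimated correlation. Without control siRNA LPS replicate 4 the Ctbp2 siRNA calls of cytokines (adjusted p = 0.166), chemokines (0.953), NF-kB genes (0.0935), AP-1 genes (0.0609) and glycolysis genes (0.0609) were lost. The same setting called lists for Ctbp1 siRNA that were not called with all libraries: cytokines (1.2e-05), chemokines (8.78e-05), NF-kB genes (0.000655) and MHC genes (0.0012) as lower, cell cycle genes (0.00938) as higher. None held with an estimated correlation (0.164 for the first 3, 0.314 and 0.723).

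Other splits of the samples into groups of the same sizes were counted for each comparison. For the Ctbp2 siRNA interaction 3 of 100 splits gave as many genes as the real one (6 when fitted on these 4 groups). The highest other split gave 309, and which libraries it grouped was not examined. Splits of an interaction can keep real siRNA labels within vehicle or LPS, so they can carry siRNA effects. Shares of such splits are therefore no clean measure of chance. For the Ctbp1 siRNA interaction 8 of 100 splits gave as many as the real 1, with 16 at most, so chance is not excluded. The other designs have 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes. Real and highest other counts were 5859 and 0 for LPS, 35 and 3 for Ctbp1 siRNA in vehicle, 76 and 1 for Ctbp2 siRNA in vehicle, 2 and 1 for Ctbp1 siRNA in LPS, 4 and 3 for Ctbp2 siRNA in LPS, 138 and 1 for Ctbp2 siRNA against Ctbp1 siRNA, and 3272 and 0 for the knockout.

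Control siRNA LPS replicate 4 showed a weaker LPS response than replicates 1 and 3. Vehicle RNA mixed into it would give the same share from induced and repressed genes, but the median share was 0.0625 from 127 repressed genes (quartiles 0.0356 to 0.0937) and 0.288 from 135 induced genes (0.184 to 0.392), which argues against mixing as the whole cause. Scaling is argued against too, since the induced genes stayed at −0.53 on the log2 scale after median-of-ratios scaling. A culture that responded later or less to LPS could give this pattern, and no biological explanation was tested.

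Of 35 interferon response genes 10 were called higher with Ctbp2 siRNA in vehicle, and the list call was lost with an estimated correlation (adjusted p = 0.121). LPS-treated RNA in those libraries is argued against by a median share of 0 from 126 other induced genes (quartiles −0.0019 to 0.0031), against 0.049 from 16 list members (0.0202 to 0.0805). Composition of TPM is argued against by 13 members called higher after median-of-ratios scaling. A response to the Ctbp2 siRNA duplex itself cannot be told apart from loss of Ctbp2: the Ctbp1 duplex left the list at 0.03 (0.0275), but neither a separate Ctbp2 duplex nor a knockout without LPS was analysed here. Loss of CtBP2 stays a candidate explanation, as a hypothesis.

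With Ctbp2 siRNA in LPS more genes were called lower than higher. Composition of TPM could give this, since 61.1% of calls were higher after median-of-ratios scaling. Without control siRNA LPS replicate 4 36.0% were higher, between the bounds set for and against that library, so its part cannot be told apart. The scaling moved the median of all tested genes from −0.05 to 0.01 on the log2 scale, so it would also remove a true broad fall. Whether there is a true excess of lower genes cannot be told from these values.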

How the results depend on the processing

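Median-of-ratios scaling, and fits without control siRNA LPS replicate 4 for Ctbp1 siRNA or Ctbp2 siRNA in vehicle, Ctbp2 siRNA against Ctbp1 siRNA, lists, classes and overlaps, were chosen after the data were seen; the other alternatives were planned. TPM keeps no depth, so the limit it sets is unknown. Called genes of the naming rule kept direction and call in all settings for 42 of 42 in the knockout, 36 of 37 with LPS, 19 of 35 for Ctbp2 siRNA against Ctbp1 siRNA, 7 of 25 for Ctbp2 siRNA in vehicle, 2 of 29 for Ctbp2 siRNA in LPS, 3 of 9 and 2 of 6 for Ctbp1 siRNA in vehicle and LPS, and 0 of 6 and 0 of 1 for the interactions of Ctbp2 and Ctbp1 siRNA. For shifts not due to fewer samples or more genes tested, the cause was not tested.

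Without a filter on low values the count of called genes was 9783 for LPS, 45 for Ctbp2 siRNA in vehicle, 132 in LPS, 227 for Ctbp2 siRNA against Ctbp1 siRNA, and 2 and 0 for the Ctbp1 and Ctbp2 interactions (8 for the latter as reported by limma, with 654 at an unadjusted p under 0.05). Without the trend limma called 7 for Ctbp1 siRNA in vehicle, 46 for Ctbp2 siRNA in vehicle, 7 for Ctbp1 siRNA in LPS, and 0 and 5 for the interactions (520 for the former at an unadjusted p under 0.05 as reported). Quantile normalization gave 138 for Ctbp2 siRNA in LPS and 225 against Ctbp1 siRNA. With only the groups in the contrast counts were 35 and 2 for Ctbp1 siRNA in vehicle and LPS, 4 for Ctbp2 siRNA in LPS and 138 against Ctbp1 siRNA.

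Median-of-ratios scaling gave 27 for Ctbp1 siRNA in vehicle, 0 and 2 for the interactions and 330 for Ctbp2 siRNA against Ctbp1 siRNA. The knockout medians of LPS-induced and LPS-repressed genes were then 0.086 and 0.068. Calls in the same direction were 2 for both siRNAs in LPS and 47 for Ctbp2 siRNA in LPS with the knockout. Ctbp1 turned to 0.036 with LPS (adjusted p = 0.62). List calls numbered 4 with an estimated correlation against 50 as reported. With a 2-fold minimum calls in the same direction were 0 for both siRNAs in LPS, 0 for Ctbp2 siRNA with the knockout and 1 for Ctbp1 siRNA with the knockout.

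Leave-one-out counts ranged from 5757 to 6073 for LPS, 5 to 43 and 21 to 147 for Ctbp1 and Ctbp2 siRNA in vehicle, 6 to 133 and 107 to 330 in LPS, 0 to 9 and 1 to 38 for the Ctbp1 and Ctbp2 interactions, 162 to 1066 for Ctbp2 siRNA against Ctbp1 siRNA, and 2774 to 3069 for the knockout. Without control siRNA LPS replicate 4, 57 lists were called. Calls in the same direction were then 17 for both siRNAs, 41 for Ctbp1 siRNA with the knockout and 27 for Ctbp2 siRNA with it. Medians of induced and repressed genes were −0.09 and 0.12 for Ctbp1 siRNA, −0.01 (−0.0090, reversed from 0.0548) and −0.03 for Ctbp2 siRNA, and 0.14 and 0.09 for the knockout.

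With the replicate number as a block counts were 34 for Ctbp1 siRNA in vehicle, 185 and 457 for Ctbp2 siRNA in vehicle and LPS, 0 and 14 for the interactions, and 914 for Ctbp2 siRNA against Ctbp1 siRNA. Of 45 pairs of BMDM libraries with the same number 21 correlated above 0.1 (−0.15 to 0.324). The median was 0.090 for pairs with the same number and −0.029 for other pairs. Each library was also matched to the 3 libraries of each other group, and in 67.8% of these matches it correlated best with its own number. For Ctbp2 siRNA and control in LPS all 3 pairs were above 0.1 (0.103, 0.111 and 0.191). In J774.1 cells 1 of 3 pairs was above 0.1, and 66.7% of matches were best with the same number. That is a hint of pairing from the data, and the labels name none.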

Other observations

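In the double knockout 34 of 35 interferon response genes were higher while Ifnb1, the gene of the interferon itself, was lower (13.0 ± 1.10 against 35.7 ± 1.40 TPM, SD, n = 3; −1.40, adjusted p = 1.04e-06). Il6 was lower too (−1.36, 7.85e-06), while Cxcl10 was higher (1644 ± 83.6 against 717 ± 19.9 TPM; 1.20). These genes were chosen after their values were seen.

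With Ctbp2 siRNA the interferon list had a median of 0.35 in vehicle and −0.12 in LPS, where it was not called with all libraries (adjusted p = 0.196). Without control siRNA LPS replicate 4 its median in LPS was −0.23 with 4 genes lower, and the list was called (8.26e-07; adjusted p = 0.401 with an estimated correlation). After median-of-ratios scaling it was at 0.0486. No explanation of the difference between vehicle and LPS was tested.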
